A study of Mus musculus with 2 samples.

How the data were processed

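Single-cell 5' RNA sequencing had been carried out on CD45-positive cells of 4 C57Bl6 mice, 2 with floxed Havcr2 alleles as controls (WT1, WT2) and 2 in which Havcr2 was targeted (KO1, KO2). Per the labels' protocols, MC38-OVAdim cells were injected under the skin, tissues were digested enzymatically, tumour cells were enriched on a density gradient, and dendritic cells were enriched in the sort. Oligo-tagged CD45 antibodies marked the tissue and mouse of each cell, and 2 GEO samples, each a droplet channel with 1 WT and 1 KO mouse, held the 3 tissues of every mouse, which gives 12 samples. Per the submitters' processing notes, Cell Ranger 3.0.2 and the genome build mm10 were used; how tags were assigned to cells and how cells and genes were filtered are not given in the sources used here. The authors deposited the matrix as natural log values, ln(1 + 10000 × UMIs of the gene / UMIs of the cell), for 12638 genes in 12458 cells, with the mouse and tissue of every cell.

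The back-transformed values summed to 10000 in every cell, and 100% of them were whole multiples of 1 UMI within 0.01, so the UMIs behind them were recovered. Every gene was found in at least 46 cells, and cells held 499 to 7531 genes and 687 to 131217 UMIs. No cell was removed; 706 cells had 5% or more mitochondrial UMIs and 1 had fewer than 500 genes. The samples held 3031124 to 28498154 UMIs in total. The depth was unequal, with medians of 15191 UMIs per cell in tumour, 4520 in dLN and 4633 in ndLN, so genes low in a lymphocyte were often not detectable. Scrublet, run through scanpy, marked 28 cells (0.225%) as doublets; at so low a share the caller was taken not to have worked, and no cell was removed on it. The sources used here do not say whether doublets were removed before.

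Cells were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method (leidenalg 0.10.2, resolution 1, seed 0), which gave 30 clusters. Clusters were named from marker genes fixed beforehand, called "like" the cell type, and kept by number where leading genes or markers of another type spoke against a name. Genes that define a cluster were not counted as results. Clusters may hold other boundaries than those of the study, since names were rebuilt here.

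A count model had been chosen before the data were examined, together with the comparisons, alternatives, markers and 17 gene lists. Since the deposited unit was the natural log, per-mouse means of log2(1 + UMIs per 10000) were taken for each class and tissue and tested with limma 3.58.1 in R 4.3.3 (trend, with 1 spread shared by all genotype and tissue groups of a class). Samples needed 20 cells of a class and genes a UMI in 5% of its cells. P values are two-sided and adjusted by Benjamini-Hochberg at 0.05 over the genes of a comparison. There were 19 comparisons of KO with WT in 11 classes, of which 6 classes with 10 comparisons have a full account. Tissues of the same mice were compared with the mouse as a term. Cell numbers were compared by limma-voom with the cells of a sample as library size. The planned test of tumour minus dLN genes within a class, and of the genotype difference between those tissues, could not be made, because no class had 20 cells in both tissues in more than 1 mouse.

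Gene lists were tested with camera (preset correlation 0.01), with an estimated correlation, and with fry, on lists with at least 3 measured genes, adjusted over the lists of a comparison. Camera sets a list against the other genes and fry tests whether the genes of a list move one way. No list passed with an estimated correlation in any comparison (lowest adjusted p = 0.210). By fry none passed in the 10 full accounts (lowest adjusted p = 0.0606, T cell checkpoint genes in macrophage-like cells), and elsewhere MHC class II genes passed in cluster 8 of ndLN (0.0477). Lists that did not pass camera in the full accounts were NADPH oxidase and antioxidant (lowest adjusted p = 0.138), glycolysis and hypoxia (0.260), cytotoxic effector (0.428) and T cell checkpoint genes (0.308). In the other classes the cytotoxic effector list passed downward in cluster 8 of dLN (0.0498). The T cell checkpoint list holds the targeted Havcr2, its 1 gene past the threshold in cDC1-like cells of dLN, so its downward pass there (adjusted p = 0.0145 by camera and 0.0293 by fry, median 0.00 over 5 genes) is not counted as a result. The sex-linked list had too few genes to be tested. The single value of 1 interferon gamma gene is not reported here.

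The genes named are Havcr2 in every class and, per comparison, genes past the threshold whose groups do not overlap and whose mean is above the median of genes, up to 10 in each direction. List members past the threshold were added, and Il1b, Il18, Nlrp3, Casp1, Cd274 and Ccr7 in myeloid and Gzmb, Ifng, Pdcd1 and Tcf7 in T cell classes whatever their test. Where fewer than 5 genes passed, those with the smallest p in each direction are given as values that did not pass. Tissue genes follow the same rule with 5 in each direction and all 4 mice changed the same way.

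The labels say that each channel held 1 WT and 1 KO mouse, so the channel pairs the mice. As a check, deviations of the mice of a channel from their genotype means correlated at 0.675 in macrophage-like and 0.376 in monocyte-like cells of tumour, and from -0.202 to 0.675 over the 19 comparisons. The model with the channel as a block was an alternative. In tumour macrophage-like and monocyte-like cells it left 1 residual degree of freedom, against 36.3 and 15.9 prior ones taken from all genes. Its calls there rest mainly on this spread shared over genes. The other alternatives were each mouse left out, median centring, no detection filter, 10 or 50 cells per sample, stricter cell filters, only the samples of 1 tissue, tissues summed, log2 of the mean plus 1, and limma-voom on recovered UMIs with the mouse as a random term. Shares were recomputed over dendritic cells alone, with trimmed-mean factors over classes, at Leiden resolution 0.5 (22 clusters). Chosen after the data were seen were limma-voom for classes of 1 tissue, the block for Havcr2, the dLN minus ndLN form of the genotype difference by tissue, unweighted log2 shares, and clusters made without the 604 called genes (28 clusters, 93.9% of cells in the same class).

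The test was tested on simulated cells with 200 changed genes. Of genes changed 4-fold it recovered 91.8% in macrophage-like (9885 genes) and 93% in monocyte-like cells of tumour (8788 genes), 69.8% in CD8 T-like cells of dLN (6338 genes), 42.4% in cDC2-like cells of ndLN (8385 genes) and 32.3% in mature DC-like cells of dLN (7469 genes). Of genes changed 2-fold it recovered 13.3%, 21.9%, 17.2%, 5% and 2.04% in the same order. In these simulations 2.08% to 6.56% of calls were false, and 5.04% to 12.3% with the channel as a block (12.3% in cDC2-like cells of ndLN). UMIs were Poisson draws with independent effects of mouse and sample (SD 0.15 on the natural log scale), in a single run per comparison. No channel effect and no mix of clusters was simulated. The shares thus do not describe the real fits where these are present, as in macrophage-like cells, whose channel deviations correlated at 0.675. Gene positions are those of mm10.

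Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.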

Results

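The data held 12458 single cells from tumours and lymph nodes of 4 mice bearing subcutaneous MC38-OVAdim tumours, a colon carcinoma line expressing ovalbumin. In 2 mice (KO1 and KO2) the gene of TIM-3, Havcr2, had been targeted, and 2 mice with floxed alleles (WT1 and WT2) were the controls. From each mouse the tumour, the tumour-draining lymph node (dLN) and a non-draining lymph node (ndLN) were sorted for CD45-positive cells with enrichment of dendritic cells (DC), which gave 12 samples. Each of 2 droplet channels held 1 WT and 1 KO mouse. WT mice contributed 6604 cells and KO mice 5854. Samples ranged from 473 cells (KO2 tumour) to 1691 cells (WT1 tumour). The median depth per cell was 15191 unique molecular identifiers (UMIs) in tumour, 4520 in dLN and 4633 in ndLN. Within tumour the sample medians were 14516 and 13877 UMIs in WT and 16751.5 and 15360 in KO. Within dLN they were 5285 and 4726 in WT and 4256.5 and 3778 in KO. Classes are called "like" a cell type from marker genes alone. Gene differences are KO minus WT in the mean of log2(1 + UMIs per 10000), a scale that understates the change of low genes, with 2 mice per genotype.

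Havcr2 encodes TIM-3, an inhibitory receptor of T cells and myeloid cells, and was compared first as a check of the genotype labels. The gene lies on chromosome 11 from 46454935 to 46481255 on the plus strand of mm10. Among the classes compared it was highest in WT cDC1-like cells of dLN, the cross-presenting dendritic cells, where WT1 had 1.24 and WT2 1.18 UMIs per 10000 against 0.00920 in KO1 and 0.0346 in KO2. There it fell by 1.01 on the log2 scale (SE 0.0931, adjusted p = 1.20e-07), and cells with a UMI made up 85% and 68.2% of WT against 1.47% and 6.25% of KO cells. In tumour macrophage-like cells it fell by 0.55 (SE 0.0323, adjusted p = 9.07e-04), from 0.677 and 0.566 to 0.0481 and 0.0319 UMIs per 10000. In tumour monocyte-like cells it fell by 0.46 (SE 0.0431, adjusted p = 0.00129), from 0.910 and 1.02 to 0.308 and 0.276, and 22.7% and 24.4% of KO cells still had a UMI. In cDC2-like cells, which prime CD4 T cells, the differences of -0.18 in dLN and -0.13 in ndLN did not pass (adjusted p = 1.00 and 0.899). Levels there were low but fell in both KO mice, from 0.284 and 0.157 to 0.0441 and 0 UMIs per 10000 in dLN. In ndLN they fell from 0.179 and 0.181 to 0.0787 and 0. B-like cells of dLN, which should lack the gene, had it in at most 0.140% of cells at median depths of 2890.5 to 3343 UMIs, against medians of 21643.5 to 23841 UMIs in macrophage-like and 11148.5 to 12662 in monocyte-like cells. No UMI was found in 812 CD8 T-like cells of dLN, which allows up to 0.369% of cells with one, nor in 496 CD4 T-like cells of dLN, which allows up to 0.605%. Without KO1 the macrophage difference was -0.55 and no longer passed (adjusted p = 0.0901; 0.0497 or lower without each other mouse), with the lone KO sample assumed to vary like the other groups. The sources used here do not say which exons were removed, and a 5' library can still count a shortened transcript.

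**Figure D1:**
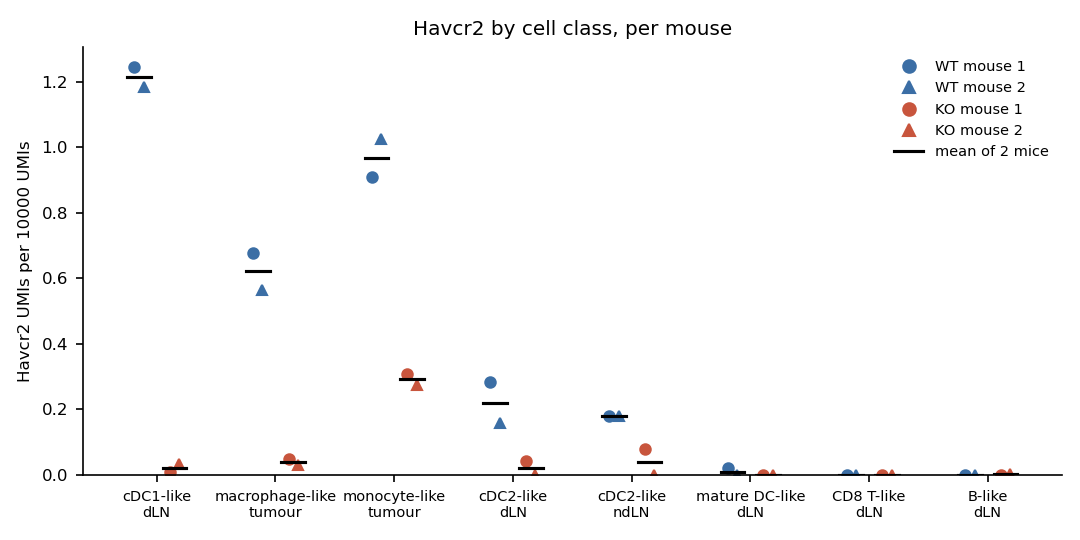
Havcr2 UMIs per 10000 UMIs (vertical axis) in 8 groups of cells by class and tissue, with a point for each mouse and a bar at the mean of the 2 mice of a genotype. Both KO mice lie below both WT mice in cDC1-like (0.00920 and 0.0346 against 1.24 and 1.18), macrophage-like and monocyte-like cells.

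Tumour monocyte-like cells of KO1 and KO2 (409 and 115 cells) were compared with those of WT1 and WT2 (467 and 428). Differences need not come from loss of TIM-3, since effects of a transgene or of the targeted locus cannot be told apart from it here. These are weighed below for Itgax, Plcb4 and 2310031A07Rik. Havcr2 was also only partly lost. Counted over all tissues, 72.3% of the WT level was left in cluster 12 and 26.6% in cluster 2, the clusters of this class. Cluster 12 held 80 and 20 KO tumour cells beside 3 and 17 of dLN and 2 and 9 of ndLN, so its value is not of tumour alone. The nitric oxide synthase Nos2 rose by 0.29 (SE 0.0408, adjusted p = 0.0236), and Fth1, the ferritin heavy chain, by 0.62 (SE 0.0881, adjusted p = 0.0236). Socs1, a feedback inhibitor of cytokine signalling, rose by 0.48 (adjusted p = 0.0397) and the neutrophil chemokine Cxcl2 by 0.45 (adjusted p = 0.0449). Rgs1 (0.59), Selm (0.36), the integrin gene Itgax (0.34), the elastase Mmp12 (0.25) and the cystine transporter Slc7a11 (0.23) also rose. In all, 13 of 8720 genes rose and 2 fell. Among the 15, Upp1 and Chil3 define a cluster of this class and are not counted as results, which leaves 13. The risen genes 2310031A07Rik, Plcb4 and Mmp13 fell outside the naming rule and were named after their values were seen. The interferon gamma response list had 10 of 11 members above 0, with Cxcl9 at 0.56 (SE 0.145), Cxcl10 at 0.53 (SE 0.118) and Gbp2, which defines a cluster of the class, at 0.32. No member passed over all genes and 10 passed when adjusted over the list alone (list adjusted p = 5.85e-12 by camera). MHC class I (11 of 11 above 0, adjusted p = 2.41e-04), MHC class II (9 of 10, 3.89e-04), DC maturation (13 of 15, 8.92e-05; Socs1 over all genes, 3 adjusted over the list alone) and type I interferon (11 of 14, 0.0272) passed in the same direction. No member of the MHC and type I interferon lists passed, over all genes or adjusted over the list alone. The list of inflammatory cytokines and NF-kB targets passed upward (adjusted p = 0.0211) with 5 of 10 members above 0, Cxcl2 over all genes and 2 adjusted over the list alone. The inflammasome list passed upward with 10 of 16 members above 0 (adjusted p = 0.0129; 0 over all genes, 1 adjusted over the list alone). Its central genes were near 0, with Il1b at -0.11, Casp1 at 0.06, Il18 at -0.01 and Nlrp3 at 0.12 (adjusted p from 0.497 to 0.907). The 8 mitochondrial genes were all below 0 (adjusted p = 0.0211), with 0 members past the threshold adjusted over the list alone. The list of TIM-3 and its reported ligands also passed downward (0.00159), but it contains the targeted Havcr2, its 1 member past the threshold, so it is not counted as a result on the ligands. Cd274, the PD-L1 gene, was 0.29 higher and did not pass (adjusted p = 0.0567), but passed with the channel as a block (adjusted p = 0.00133). No list passed with an estimated correlation (adjusted p = 0.498 for 7 lists and 0.596 for type I interferon and the mitochondrial genes). With the channel as a block 133 genes passed, 100 up and 33 down, with the 15 among them, while 6 passed by limma-voom and 0 without the detection filter. Of the 133, 5 define a cluster of this class (Cfb, Chil3, Hp, Ly6i and Upp1) and are not counted as results, which leaves 128. The count of KO versus WT genes, monocyte-like cells of tumour, was 159 without WT1, 216 without KO1, 85 without KO2 and 22 without WT2. Without WT2, Cxcl2 (adjusted p = 0.0665), Mmp12 (0.0753), Slc7a11 (0.0630) and Socs1 (0.0724) no longer passed, and without KO1 Fth1 did not (0.0821).

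In tumour macrophage-like cells, antigen presentation and interferon gamma genes lay above WT in KO as whole lists, while single genes of these lists passed only with the channel as a block. All 11 measured interferon gamma genes were higher (Cxcl9 by 0.65, SE 0.246; Gbp2 by 0.41, SE 0.183), as were all 10 MHC class II genes (Cd74 by 0.65, SE 0.325; H2-Eb1 by 0.56, SE 0.375) and all 11 MHC class I genes (B2m by 0.26). The lists passed camera at adjusted p = 3.66e-08, 2.97e-05 and 3.36e-05, with 0 members past the threshold over all genes by limma and 0 adjusted over the list alone. With an estimated correlation none did (adjusted p = 0.410 for each list of this class named here). With the channel as a block all 11 interferon gamma genes, 7 MHC class II genes and 5 MHC class I genes passed. That fit left 1 residual degree of freedom, so these calls rest mainly on the spread shared over genes. DC maturation (12 of 16 above 0, adjusted p = 2.85e-04, 0 adjusted over the list alone) and the naive T cell list (7 of 8, 0.00107, 1 adjusted over the list alone, with Il7r, the IL-7 receptor, at 0.21) passed upward. The list of TIM-3 and its reported ligands passed downward (1.93e-04), with the targeted Havcr2 as its 1 member past the threshold, and is not counted as a result on the ligands. The inflammasome list passed upward with 11 of 16 members above 0 (adjusted p = 0.0327; 0 adjusted over the list alone), with Il1b at -0.01, Il18 at -0.01, Nlrp3 at 0.01 and Casp1 at 0.13. The proliferation list passed downward (0 of 11 above 0, adjusted p = 2.01e-11), but its genes define cluster 10 of this class and it is not counted as a result. Cluster 10 held 26.7% and 25.3% of WT and 15.9% and 25% of KO macrophage-like cells, beside clusters 3 and 9. Of 9789 genes 3 passed, Havcr2 downward and 2 genes named outside the rule after their values were seen. These were 2310031A07Rik, which lies 7.69 kb from Havcr2 (0.23 higher, SE 0.0212, adjusted p = 0.0144), and Plcb4 (0.09 higher, SE 0.00829, adjusted p = 0.0144). The next genes, Dusp1 at 0.77 and Rsrp1 at 0.65 (adjusted p = 0.146 each) and the lipase Lpl at -0.08, did not pass. With the channel as a block 550 genes passed, 249 up and 301 down, among them Dusp1, Rsrp1, Casp1 (adjusted p = 0.0148) and Cd274 (0.16 higher, adjusted p = 0.00171), while 5 passed by limma-voom and 0 without the detection filter. Of the 550, 17 define a cluster of this class and are not counted as results, which leaves 533. The count of KO versus WT genes, macrophage-like cells of tumour, was 104 without WT1, 1 without WT2, 0 without KO1 and 2 without KO2, where 2310031A07Rik lost its call without WT2 (0.0853) and KO1 (0.0901), and Plcb4 without WT2 (0.114), KO1 (0.147) and KO2 (0.140).

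**Figure D2:**
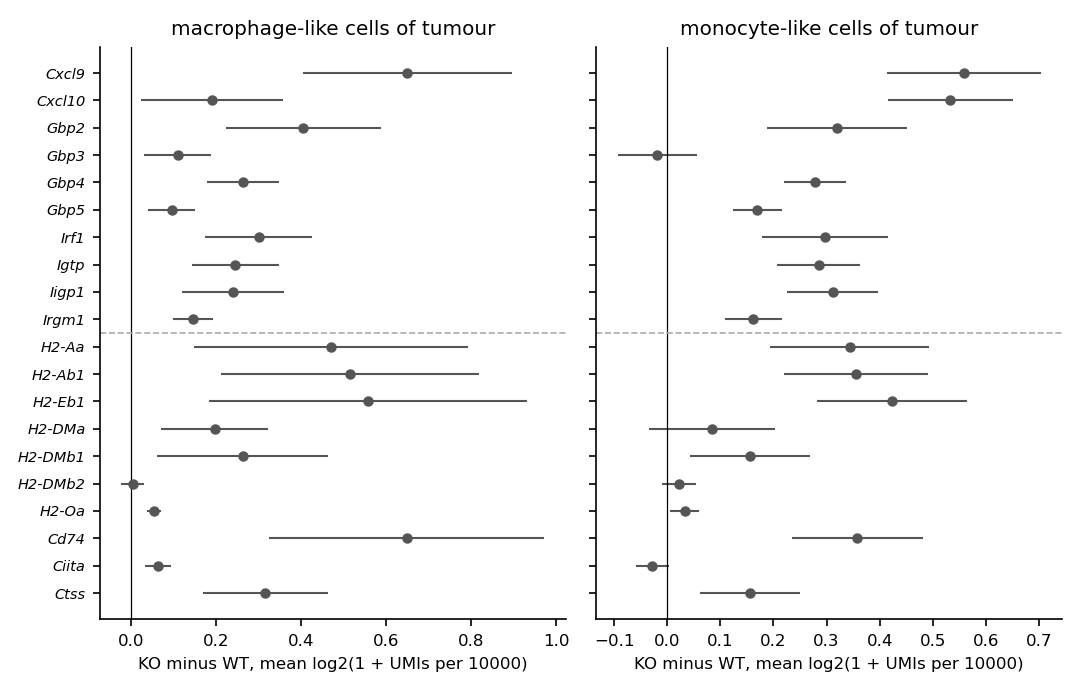
Log2 difference KO minus WT (horizontal axis) of 10 interferon gamma response and 10 MHC class II genes in tumour macrophage-like and monocyte-like cells, with points at the fitted difference and bars of 1 standard error. In macrophage-like cells all genes drawn lie above 0, and in monocyte-like cells 9 of 10 of each list do.

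Mature DC-like cells, the migratory Ccr7-positive state that carries antigen to lymph nodes, were compared within dLN (224 and 166 WT and 43 and 24 KO cells) and ndLN (123 and 147, and 64 and 27). In dLN the MHC class II chain H2-Ab1 rose by 1.09 (SE 0.190, adjusted p = 0.0418) and Gpr183, a receptor for oxysterols that guides cell position, by 0.54 (SE 0.0850, adjusted p = 0.0349). All 9 measured MHC class II genes were above 0 (adjusted p = 8.04e-06; H2-Ab1 over all genes, 3 adjusted over the list alone), with H2-DMa at 0.53. The stress list of immediate early and heat shock genes had 10 of 11 members above 0 (adjusted p = 1.65e-09; 0 over all genes, 7 adjusted over the list alone), with Hspa1a at 1.66 (SE 0.316, adjusted p = 0.0885). Naive T cell genes passed upward (6 of 7 above 0, adjusted p = 0.0106; 0 over all genes, 1 adjusted over the list alone). These 3 lists did not pass with an estimated correlation (adjusted p = 0.210). The inflammasome genes Il1b (0.31 higher) and Casp1 (-0.12), and Cd274 (0.27) and Ccr7 (0.47), did not pass (adjusted p from 0.430 to 0.719). The third gene past the threshold of 7208, Ccl5, defines cluster 7 and is not counted as a result. Cluster 7 held 64.7% and 65.7% of WT but 32.6% and 29.2% of KO mature DC-like cells of dLN, and cluster 15 most of the rest, so the genotypes were drawn from different clusters. In ndLN no gene passed by limma (299 at an unadjusted p under 0.05, 0 by limma-voom). There Il1b was 0.30, Cd274 0.17 and Ccr7 0.35 higher, with adjusted p of 0.983 for each, and with the channel as a block 1 gene (Ccl5) and 2 lists passed. In dLN 7 genes passed with the channel as a block, among them Hspa1a (adjusted p = 0.0202) and the chaperone Hsp90aa1 (0.0460), and 32 by limma-voom. Of the 7, 3 define a cluster of this class (Ccl5, Epsti1 and Zmynd15) and are not counted as results, which leaves 4. The count of KO versus WT genes, mature DC-like cells of dLN, was 0 without WT1 or WT2, where H2-Ab1 had adjusted p of 0.374 and 1.00 and Gpr183 of 0.590 and 1.00, 1009 without KO1 and 358 without KO2. The count of KO versus WT genes, mature DC-like cells of ndLN, was 266 without KO1 and 1 without KO2.

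In cDC2-like cells the chemokine gene Ccl4 rose by 1.33 in ndLN (SE 0.206, adjusted p = 0.00223) and Cox6a2, a subunit of cytochrome c oxidase, by 0.80 (SE 0.0991, adjusted p = 7.66e-05). Cox6a2 had 0.328 and 0.0603 UMIs per 10000 in WT and 4.52 and 3.07 in KO. It lies on chromosome 7 from 128205435 to 128206387, 54.8 kb from Itgax. Cox6a2 also marks pDC, with a UMI in 94.1% of pDC-like cluster 14, and the pDC genes Bst2 (0.57), Tcf4 (0.47), Siglech (0.17) and Ccr9 (-0.02) did not pass in cDC2-like cells of ndLN (adjusted p from 0.899 to 0.998), where cluster 6 had Siglech in 24.6% of cells. The cDC2 genes Cd209a (0.89) and Clec10a (0.58), and Areg (0.36), did not pass in ndLN (adjusted p from 0.427 to 0.522). In dLN Cox6a2 was 0.42, Plcb4 0.22 and Cd74 0.39 higher and Il1b 0.53 lower, and no gene of 8272 passed by limma (227 at an unadjusted p under 0.05, 0 by limma-voom). MHC class II genes of dLN passed as a list (9 of 10 above 0, adjusted p = 2.71e-04; 0 over all genes, 2 adjusted over the list alone). So did the stress list (10 of 12, 0.00285) upward, and the mitochondrial (1 of 8 above 0, 0.00131) and interferon gamma genes (4 of 9 above 0, 0.0415) downward. None of these passed with an estimated correlation (adjusted p = 0.501), and the stress, mitochondrial and interferon gamma lists had 0 members past the threshold adjusted over the list alone. In ndLN the stress list was up (9 of 12 above 0) and the type I interferon (1 of 7 above 0) and interferon gamma lists (3 of 9) down, each at adjusted p = 0.0398 with 0 members adjusted over the list alone. With an estimated correlation these had adjusted p = 0.528, 0.440 and 0.440. Casp1, Nlrp3, Il18, Cd274 and Ccr7 were between -0.08 and 0.10 in both nodes and did not pass. Ccl4 lost its call without WT1 (adjusted p = 0.467) and KO1 (0.0644), where the ndLN count was 1 each, and by limma-voom 0 genes passed in ndLN. The dLN count was 6 without WT1 and 1 without KO1.

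CD8 T-like cells of the lymph nodes differed in a single gene. Hspa1a, an inducible HSP70 chaperone, rose by 0.42 in KO dLN (SE 0.0656, adjusted p = 8.71e-04), and the stress list passed with 9 of 11 members above 0 (adjusted p = 2.25e-06; 1 over all genes, 3 adjusted over the list alone). Its members Jun (0.33, adjusted p = 0.0707) and Hspa1b (0.19) did not pass alone. Hspa1a and Hspa1b are near-identical copies, and so are several H2 genes, so reads could be divided between them and their single values are uncertain. The naive and stem-like list was higher in dLN (9 of 11 above 0, adjusted p = 0.00327; 0 adjusted over the list alone), with Tcf7 at -0.04. Neither list passed with an estimated correlation (adjusted p = 0.632). In ndLN the type I interferon (1 of 5 above 0, adjusted p = 0.00212, 2 adjusted over the list alone) and MHC class I lists (2 of 11, 0.0424, 0 adjusted over the list alone) passed downward, and neither did with an estimated correlation (adjusted p = 0.484). No gene passed in ndLN by limma (276 at an unadjusted p under 0.05, 0 by limma-voom), where the interferon-induced Ifi27l2a was at -0.52 and the cytokine receptor Il7r at 0.54. Gzmb, Ifng and Pdcd1 were under the detection filter. With the channel as a block Jun passed as a second gene in dLN (adjusted p = 0.0469), and Il7r (0.0235) and mt-Nd3 (0.00545) passed in ndLN; limma-voom called 3 genes in dLN, and without the detection filter 0 passed there. Hspa1a lost its call without WT1 (adjusted p = 0.0857), KO1 (0.0992) and KO2 (0.0844). The dLN count was 2 without WT2 and 0 without KO1, and the ndLN count 4 without WT1 and 1 without KO2.

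CD4 T-like cells, compared with 148 and 135 WT and 123 and 90 KO cells in dLN, again differed in Hspa1a. It rose by 0.65 in dLN (SE 0.0987, adjusted p = 3.80e-04), and was 0.38 higher in ndLN, where it did not pass (adjusted p = 0.505). The stress list passed in both nodes, with 7 of 10 members above 0 in dLN (adjusted p = 6.36e-05; 1 over all genes, 2 adjusted over the list alone) and 7 of 10 in ndLN (0.00983; 0 and 2). All 6 type I interferon genes were above 0 in dLN (adjusted p = 0.0166; 0 adjusted over the list alone). With an estimated correlation the dLN lists had adjusted p = 0.496 and 0.531 and the ndLN list 0.898. Tcf7, a transcription factor of naive T cells, was 0.22 higher in dLN and 0.65 lower in ndLN (adjusted p = 0.999 and 0.480). No gene passed in ndLN by limma (330 at an unadjusted p under 0.05, 1 by limma-voom), where the chaperone Hspa8 was at 0.53. With the channel as a block Ddit4 (0.60 higher in dLN, adjusted p = 0.00775) and Hspa8 (ndLN, 0.0242) passed. Hspa1a lost its call in dLN without WT2 (adjusted p = 0.287) and KO1 (0.143), where the count was 0, and the dLN count was 2 without KO2. The ndLN count was 3 without WT1 and 2 without WT2.

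**Figure D3:**
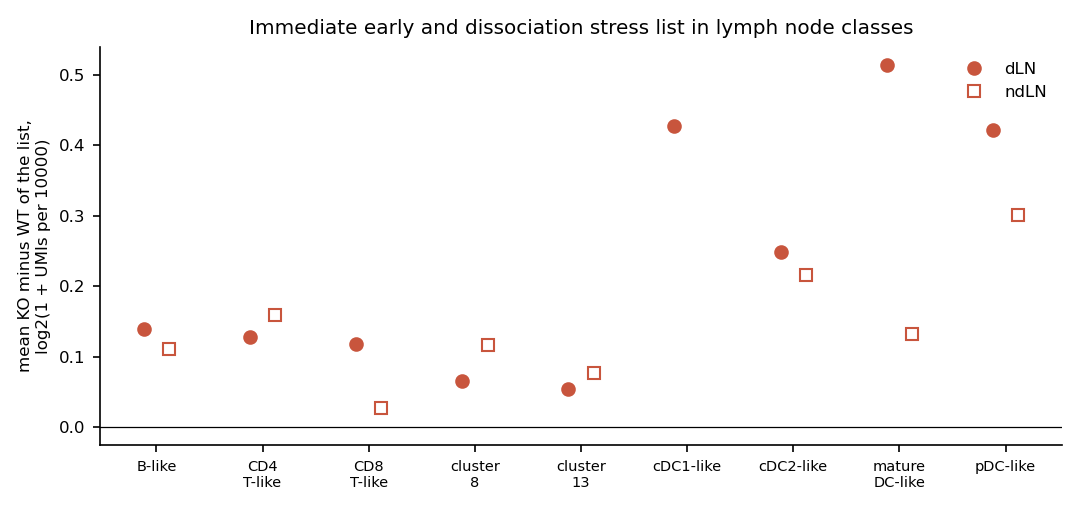
Mean log2 difference KO minus WT of the stress list (vertical axis) in each lymph node class, with filled points for dLN and open points for ndLN. Means in dLN run from 0.05 in cluster 13 to 0.51 in mature DC-like cells.

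The other 9 comparisons gave 10 calls. In cDC1-like cells of dLN, besides the fall of Havcr2, 2310031A07Rik rose by 0.88 (adjusted p = 3.23e-07), the co-chaperone Bag3 by 0.58 (0.00165), Hspa1a by 1.16 (0.0119), Gm6377 by 0.61 (0.0253) and the glucocorticoid-induced Tsc22d3 by 0.65 (0.0381). In B-like cells of dLN, held mainly by clusters 1 and 4 with cluster 4 at 25.4% and 22% of WT but 42.2% and 59.4% of KO, Jun rose by 0.50 (0.0364). In pDC-like cells the chaperone Hsph1 rose by 0.80 in ndLN (0.0117), and Cox6a2, which defines that class and is not counted as a result, passed in both nodes. Clusters 8 (CD4 T cells) and 13 (CD8 T cells), left unnamed, had 0 calls by limma (248 to 349 at an unadjusted p under 0.05, and 1 by limma-voom in cluster 13 of ndLN). The stress list passed upward in cDC1-like (12 of 12 above 0, adjusted p = 8.11e-13, 6 adjusted over the list alone), pDC-like (11 of 11, 2.80e-11, 5) and B-like cells of dLN (7 of 11, 0.00531, 3) and pDC-like cells of ndLN (10 of 11, 5.15e-04, 2), with adjusted p = 0.294, 0.332, 0.638 and 0.407 with an estimated correlation. With the channel as a block the 9 comparisons gave 15 calls. The number of KO versus WT genes, total over the comparisons of the other classes, was 357 without WT1, 136 without WT2, 6 without KO1 and 8 without KO2.

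Whether the makeup of each tissue differed between KO and WT mice was read from cell shares, which the sort for CD45 and dendritic cells also sets. Mature DC-like cells were 19.7% and 15.7% of WT dLN cells but 4.22% and 1.65% of KO cells (17.7% ± 2.78 against 2.94% ± 1.82, SD, n = 2 mice each). In ndLN they were 16.3% and 15.3% of WT and 11.2% and 2.76% of KO cells. cDC2-like cells of dLN went the other way, at 4.91% and 2.46% in WT and 11.4% and 8.03% in KO. In tumour, cDC2-like cells were 1.42% and 1.70% of WT and 0.443% and 0.423% of KO cells, and macrophage-like cells 37.4% and 36.6% against 48.0% and 49.9%. No class passed in any tissue by limma-voom (2 of 14 in tumour, 2 of 15 in dLN and 1 of 14 in ndLN at an unadjusted p under 0.05, and 0 by limma on unweighted log2 shares). The dLN differences were -2.78 on the log2 scale for mature DC-like cells (SE 0.771, adjusted p = 0.0695) and 1.44 for cDC2-like cells (SE 0.484, adjusted p = 0.103). In the mature DC-like share, KO versus WT, dLN, the difference passed with the channel as a block (adjusted p = 0.0269). As shares of dendritic cells alone this and the cDC2-like share, KO versus WT, dLN, passed (-2.40 and 1.77, adjusted p = 0.00666 each). These shares sum to a fixed total, so the fall of mature DC-like cells by itself raises the shares of other dendritic classes. The cDC2-like pass is therefore not independent of that fall. As a share of all cells that class did not pass (adjusted p = 0.103). Clustered without the called genes the mature DC-like share of all cells passed too (-2.84, adjusted p = 0.04). That setting was chosen after the data were seen. Exact permutation of 2 against 2 mice cannot go below p = 0.33.

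**Figure D4:**
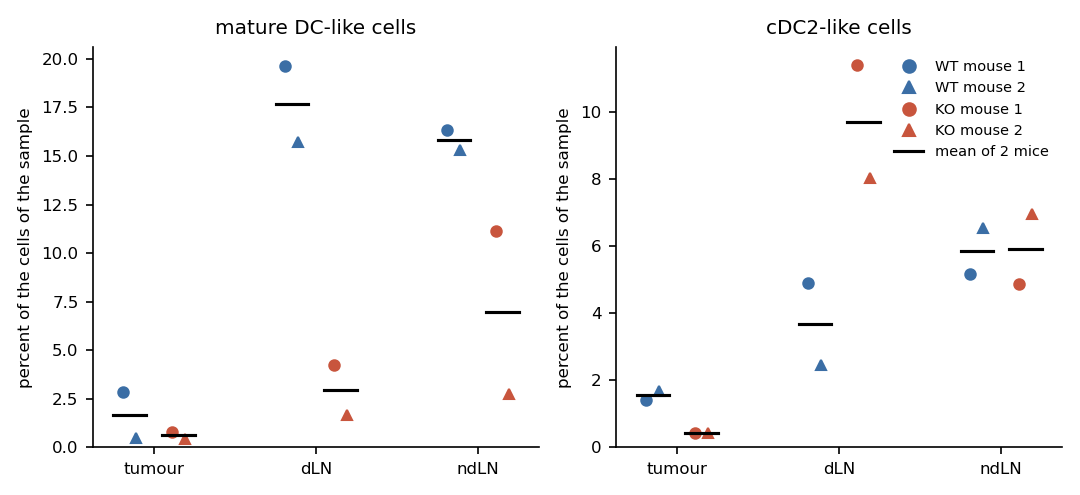
Mature DC-like cells (left) and cDC2-like cells (right) as a percent of all cells of a sample (vertical axis) by tissue, with a point for each mouse and a line at the mean of a genotype. In dLN mature DC-like cells were 19.7% and 15.7% in WT and 4.22% and 1.65% in KO.

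Tumour and dLN differed in the shares of most classes. Macrophage-like cells were 43.0% ± 6.94 of tumour cells (SD, n = 4 mice) and 0.147% of dLN cells, a log2 difference of 8.12 (SE 0.578, adjusted p = 5.70e-21). Monocyte-like cells were 31.2% ± 8.02 against 0.572% (5.92, adjusted p = 1.38e-12), and Treg-like cells, cluster 21 alone, were 1.91% against 0.0172%. Cluster 8, at 5.10% of dLN and 0.470% of tumour cells, had Foxp3 in 17.9% and Ikzf2 in 37.4% of its cells. The Treg-like shares thus do not count all Treg of the lymph nodes. CD8 T-like cells were 0.142% of tumour and 18% ± 5.96 of dLN cells (-6.63, adjusted p = 1.65e-16). B-like cells were 1.16% against 30.9% ± 13.1, and mature DC-like cells 1.14% against 10.3% (-2.82, adjusted p = 6.64e-05). The mature DC-like share, tumour minus dLN, did not pass as a share of dendritic cells (-0.28, adjusted p = 0.723) or with trimmed-mean factors over classes (-0.85, 0.254). Cluster 18, CD8 T cells led by Pdcd1, Lag3 and Gzmb, was higher in tumour by 4.33. In all, 9 of 23 classes or clusters were higher and 12 lower in tumour, while NK-like (1.16, adjusted p = 0.185) and cDC1-like cells (-1.30, adjusted p = 0.0838) did not pass. Between dLN and ndLN 1 of 16 passed, cluster 20, with the plasma cell genes Jchain and Mzb1 among its leading genes, at 1.79% of dLN and 0.540% of ndLN cells (1.83, adjusted p = 0.0343, higher in 3 of 4 mice). It did not pass without WT1 (adjusted p = 0.441), KO1 (0.344) or KO2 (0.937). Tissues differed in dissociation and, per the labels, density gradient enrichment was described for tumour.

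Within a class, few genes differed between dLN and ndLN of the same mice. In CD8 T-like cells 3 genes rose and 9 fell in dLN, among them the survival gene Bcl2 by -0.20 and the phosphatase gene Dusp5 by -0.16 (adjusted p = 0.0408 each), with Gm26532 at -0.22 (1.56e-04) and Copg1 at 0.14 (0.0408). These 4 went the same way in all 4 mice. Bcl2 and Copg1 passed in 0 of 4 fits that left a mouse out (adjusted p from 0.0540 to 0.955 and from 0.0957 to 0.955), Dusp5 not without WT2 (0.768) or KO2 (0.955), and Gm26532 not without WT2 (0.0957). In CD4 T-like cells the ribosomal and translation genes Rplp1 (-0.12, adjusted p = 0.0257) and Eef1a1 (-0.08, 0.0340) and the immediate early gene Junb (-0.53, 0.0257) fell, the last 2 outside the naming rule and named after their values were seen. In cDC2-like cells the interferon-induced genes Ifitm3 (0.75 higher), Oasl2 (0.22) and Zbp1 (0.19) had adjusted p of 0.0904 each, with no gene past the threshold by limma (651 at an unadjusted p under 0.05; no other tool was run). In mature DC-like cells no gene passed by limma (378 at an unadjusted p under 0.05), with Ccnd1 at 0.39 and Crip1 at -0.34 (adjusted p = 0.841). The other 4 classes and clusters gave 1 call in B-like (Cd74), 4 in pDC-like (lower in dLN, Nr4a3 in all 4 mice, and Nr4a1, Ccl4 and Vps37b, named outside the rule after their values were seen, in 3 of 4 mice each), 16 in cluster 8 and 3 in cluster 13 cells. The count of tissue genes, CD8 T-like cells, dLN minus ndLN, was 2 without WT2 or KO2 and 22 without KO1. The CD4 T-like count 13 without WT1, 11 without KO1 and 0 without WT2 or KO2, and the count of tissue genes, cDC2-like cells, dLN minus ndLN, 37 without WT2 and 1 without KO2.

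Whether the genotype difference itself differed between dLN and ndLN was tested as an interaction, chosen after the data were seen because no class had 20 cells in both tumour and dLN in more than 1 mouse. In CD8 T-like cells Ifi27l2a was 0.20 higher in KO dLN and 0.52 lower in KO ndLN (difference 0.73, SE 0.148, adjusted p = 0.00290). Hspa1a was 0.42 higher in dLN and 0.06 lower in ndLN (difference 0.48, SE 0.0884, adjusted p = 3.83e-04). In cDC2-like cells Ccl4 was 0.24 higher in dLN and 1.33 higher in ndLN (difference -1.10, SE 0.217, adjusted p = 0.0435). No gene passed by limma in mature DC-like (325 at an unadjusted p under 0.05) or CD4 T-like cells (297); no other tool was run. In KO versus WT by tissue, CD8 T-like cells, dLN minus ndLN, the count was 1 without WT1, 0 without WT2, 73 without KO1 and 8 without KO2. The cDC2-like count was 4 without KO1 and 0 without each other mouse, the CD4 T-like count 10 without KO1 and 4 without KO2, and in KO versus WT by tissue, mature DC-like cells, dLN minus ndLN, 1277 without KO1 and 600 without KO2.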

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

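Of the tests in this part, thinning of the stress list was chosen before its result was seen, and those of cell suspension stress, of the cDC1-like excess, of clusters, lymphocytes and sorting, and the dLN minus ndLN form of the genotype difference were chosen after.

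In 52 groups of 4 mice, 6 values lay apart from the other 3, and chance sets apart about 1 in 20 groups. Mature DC-like cells were 2.84% of WT1 tumour cells against 0.423% to 0.812% in the other mice. NK-like cells were 1.80% of WT2 dLN cells against 0.589% to 0.686%, and pDC-like cells 2.46% against 4.12% to 4.42%. In KO2, CD4 T-like cells were 6.18% of dLN cells against 12.1% to 13%, and B-like cells 34.5% of ndLN cells against 18.7% to 20.6%. The median mitochondrial share of UMIs in WT1 ndLN was 2.60% (2.595) against 2.77% to 2.79%.

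For 5 genes the KO minus WT difference in dLN differed from that in ndLN by an interaction test. The difference was 0.73 for Ifi27l2a and 0.48 for Hspa1a in CD8 T-like cells, -1.10 for Ccl4 in cDC2-like cells, -0.0775 for Cd74 in B-like cells and 0.71 for Gm42418 in cluster 13 cells (adjusted p = 0.00290, 3.83e-04, 0.0435, 0.0121 and 0.00146).

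Immediate early and heat shock genes, Hspa1a among them, lay above WT in KO dLN as a list that passed by camera in 7 of 9 classes (not in clusters 8 and 13) but in none with an estimated correlation (adjusted p from 0.210 to 0.869), with list means from 0.05 in cluster 13 and 0.12 in CD8 T-like to 0.43 in cDC1-like and 0.51 in mature DC-like cells. Lower depth of KO dLN cells as the whole cause is argued against, since at 2000 UMIs per cell at least 80.28% of the list difference was kept in B-like, CD8 T-like and CD4 T-like cells. Stress of the KO dLN suspensions before capture stays open, since a list median above 0 in 9 of 9 dLN classes restates the pattern, and the list also passed in ndLN in CD4 T-like, cDC2-like and pDC-like cells (adjusted p = 0.00983, 0.0398 and 5.15e-04, none with an estimated correlation), which stress of the dLN suspensions alone would not give. The list mean in cDC1-like cells, the class with most Havcr2 among those compared, exceeded the highest of the 3 lymphocyte classes by 0.289 (0.2894). An effect of TIM-3 loss inside the cells could give this, but so could a cell type that responds more to stress. Mature DC-like cells had a higher mean, although they held 4, 0, 0 and 0 Havcr2 UMIs in WT1, WT2, KO1 and KO2. It decides nothing on a rise that follows Havcr2, because the genotypes were drawn from different clusters in that class. Cluster 7 held 64.7% and 65.7% of WT but 32.6% and 29.2% of KO mature DC-like cells of dLN. The explanations cannot be told apart, because each KO dLN was a single suspension per mouse.

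Mature DC-like cells were 4.22% and 1.65% of KO dLN cells against 19.7% and 15.7% (mature DC-like share, KO versus WT, dLN, adjusted p = 0.0695, range 0.00666 to 0.455 over the alternatives, 0.0269 with the channel as a block and 0.00666 among dendritic cells), and 11.2% and 2.76% of KO ndLN cells against 16.3% and 15.3%. In dLN, cells moved between clusters are argued against, since cells with a UMI of both Ccr7 and Fscn1 at 2000 UMIs (17.3% and 13% of WT and 5.72% and 1.48% of KO cells, beside 2.25%, 0.661%, 2.12% and 0.230% of lymphocytes as background) were 7.297 percentage points fewer in the higher KO than in the lower WT mouse, with ranges of up to 4.30 within a genotype. More lymphocytes in the KO samples are argued against there too, since among dendritic cells alone that gap was 44.23 points, with ranges of up to 8.34. In ndLN neither is excluded, with gaps of 1.201 and 2.66 points and ranges of up to 8.999 and 29.03, since the Ccr7 and Fscn1 shares were 14.6% and 12.7% in WT against 11.5% and 2.51% in KO, with a background of 2.61%, 0%, 4.35% and 0.517%. Sorting or pooling of each tissue may have shifted the share and stays open, with dendritic cells 5.38 percentage points lower in KO dLN (-5.38), as does an effect of genotype on these cells. The genotypes overlapped in that total, at 33.1% and 23.2% of WT and 27.8% and 17.7% of KO dLN cells.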

How the results depend on the processing

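The alternatives chosen after the data were seen were limma-voom for classes of 1 tissue, the block for Havcr2, the dLN minus ndLN form of the genotype difference, unweighted log2 shares and clusters made without the called genes; the rest were planned. Of 2783 alternative values of 248 results, 2257 kept their direction and side of the threshold, 150 were weaker, 114 stronger, 216 moved and 46 reversed. The 46 belonged to 27 results and none passed the threshold in either fit (lowest adjusted p = 0.332). Of 37 single genes and classes past the threshold none changed direction, 6 passed in every alternative that left no mouse out, all of them tumour minus dLN cell shares (B-, CD4 T-, CD8 T-, macrophage-, monocyte- and pDC-like), and 16 whichever mouse was left out, while 58 others passed in an alternative alone. The replicate block of the 10x channel ended 0 single calls and added 24, and it changed no call other than those and the counts given here. For results changed below, the cause was not tested, unless fewer genes, samples or cells are named. Scaling by median ratios or trimmed means of counts and a DESeq2 test were left out because the deposited unit was a natural log, although the recovered UMIs would have allowed them. Tumour minus dLN genes and their genotype difference could not be tested.

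Counts below are of KO versus WT genes, macrophage-like cells of tumour (3), KO versus WT genes, monocyte-like cells of tumour (15), KO versus WT genes, mature DC-like cells of dLN (3), KO versus WT genes, mature DC-like cells of ndLN (0), KO versus WT genes, cDC2-like cells of dLN (0) and KO versus WT genes, cDC2-like cells of ndLN (2). They are also of KO versus WT genes, CD8 T-like cells of dLN (1), KO versus WT genes, CD8 T-like cells of ndLN (0), KO versus WT genes, CD4 T-like cells of dLN (1), KO versus WT genes, CD4 T-like cells of ndLN (0) and KO versus WT genes, total over the comparisons of the other classes (10). With the replicate block they were 550 in macrophage-like, 133 in monocyte-like, 7 and 1 in mature DC-like of dLN and ndLN, 2 and 2 in CD8 T-like and 2 and 1 in CD4 T-like cells. With no filter on detection they were 0 in macrophage-like and monocyte-like, 1 in mature DC-like of dLN, 1 in cDC2-like of ndLN, 0 and 1 in CD8 T-like and 22 and 7 in CD4 T-like cells, and 43 in total elsewhere. Summed over tissues they were 3 in monocyte-like, 11 and 11 in mature DC-like, 2 in cDC2-like of dLN, 0 in CD8 T-like of dLN and 2 and 2 in CD4 T-like cells. As log2 of the mean plus 1 they were 5 in macrophage-like, 8 in monocyte-like, 1 in cDC2-like of ndLN, 2 in CD8 T-like of dLN and 2 in CD4 T-like cells of ndLN. By limma-voom they were 32 in mature DC-like of dLN, 0 in cDC2-like of ndLN, 3 in CD8 T-like of dLN, 1 in CD4 T-like of ndLN, 5 in macrophage-like and 6 in monocyte-like cells. With under 5% mitochondrial UMIs and 500 or more genes per cell they were 4 in monocyte-like, 1 in mature DC-like of dLN and 2 in CD8 T-like cells of dLN. With only the 4 samples of a tissue they were 2 and 2 in CD8 T-like cells and 29 elsewhere. In mature DC-like cells of dLN the count was 1 with median centring and 1 with 10 or more cells per sample. Leaving out each mouse gave 0 to 104 in macrophage-like, 22 to 216 in monocyte-like, 0 to 1009 and 0 to 266 in mature DC-like, 0 to 6 and 1 to 2 in cDC2-like, 0 to 2 and 0 to 4 in CD8 T-like and 0 to 2 and 0 to 3 in CD4 T-like cells, and 6 to 357 elsewhere, with the lone sample assumed to vary like the other groups.

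With an estimated correlation the lists past the threshold went to 0 in macrophage-like (8), monocyte-like (9, as in the former with the list that holds Havcr2 itself), mature DC-like of dLN (3), cDC2-like of dLN (4) and ndLN (3), CD8 T-like of dLN (2) and ndLN (2) and CD4 T-like cells of dLN (2) and ndLN (1). With median centring they were 1 in CD8 T-like, 1 in cDC2-like and 1 in mature DC-like cells of ndLN, and with the replicate block 2 in mature DC-like cells of ndLN. Leaving out each mouse gave 5 to 10 in monocyte-like, 2 to 5 and 0 to 3 in mature DC-like, 0 to 4 and 1 to 5 in cDC2-like, 1 to 5 and 0 to 7 in CD8 T-like, and 0 to 2 and 0 to 1 in CD4 T-like cells.

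Tissue genes, CD4 T-like cells, dLN minus ndLN, numbered 3 and were 0 with median centring, 0 with no filter on detection and 0 with no replicate block of the mouse; in CD8 T-like cells (12) the last 2 settings gave 0 and 0. Leaving out each mouse gave 0 to 13 in CD4 T-like, 2 to 22 for tissue genes, CD8 T-like cells, dLN minus ndLN, and 0 to 37 for tissue genes, cDC2-like cells, dLN minus ndLN. For KO versus WT by tissue, CD8 T-like cells, dLN minus ndLN, it gave 0 to 73, and 0 to 10 in CD4 T-like and 0 to 4 in cDC2-like cells. For KO versus WT by tissue, mature DC-like cells, dLN minus ndLN, it gave 0 to 1277. Classes past the threshold in KO versus WT shares of dLN were 1 with the replicate block and 1 clustered without the called genes, and in dLN minus ndLN shares 0 at Leiden resolution 0.5 and 0 to 1 without each mouse. The cDC2-like share, tumour minus dLN (-2.83), did not pass as a share of dendritic cells (-0.61) or with trimmed-mean factors over classes (-0.78), which also ended the call of the cluster 20 share, tumour minus dLN (-3.00 to -0.88). The adjusted p of the mature DC-like share, KO versus WT, dLN, ranged from 0.00666 to 0.455 over the alternatives, and its difference from -3.39 to -2.04.

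Reversed values were all of results that had not passed. For median centring it was Casp1 in mature DC-like cells of ndLN (0.0182). Under the cell filter they were Ccr7 in cDC2-like cells of ndLN (0.00387) and Nlrp3 in macrophage-like cells (-0.000995). Summed over tissues they were Ccr7 (0.0217) and Il1b (-0.14) in cDC2-like cells of ndLN, Tcf7 in CD4 T-like cells of dLN (-0.12) and Tubb2a in CD4 T-like cells of ndLN (-0.00967). As log2 of the mean plus 1 they were Ccr7 in macrophage-like cells (-0.00128) and Tcf7 in CD8 T-like cells of dLN (0.0458). By limma-voom they were Il18 (0.27) and Nlrp3 (0.0437) in cDC2-like cells of ndLN and Nlrp3 in macrophage-like cells (-0.0268). As a share of dendritic cells only, where the denominator also fell in KO tumour, they were cDC1-like share, KO versus WT, tumour (0.61), cDC2-like share, KO versus WT, tumour (0.00608) and mature DC-like share, KO versus WT, tumour (0.0589). With trimmed-mean factors over classes they were cDC2-like share, KO versus WT, ndLN (-0.0451) and monocyte-like share, KO versus WT, tumour (0.11). Clustered without the called genes the cDC2-like share of ndLN was -0.00702.

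Leaving out each mouse gave these ranges for single values, of which all but Havcr2 reversed. Casp1 ran from -0.13 to 0.30 in cDC2-like cells of dLN, -0.0802 to 0.14 in ndLN, -0.13 to 0.12 in mature DC-like cells of ndLN and -0.00612 to 0.12 in monocyte-like cells. Ccr7 ran from -0.0642 to 0.27 in cDC2-like cells of dLN, -0.18 to 0.13 in ndLN and -0.00997 to 0.0253 in macrophage-like cells. Cd274 ran from -0.17 to 0.00484 in cDC2-like cells of dLN, -0.0283 to 0.56 in mature DC-like cells of dLN and -0.0166 to 0.36 in ndLN. Il18 ran from -0.0589 to 0.0483 in cDC2-like cells of ndLN, -0.0194 to 0.00717 in macrophage-like and -0.0297 to 0.00422 in monocyte-like cells. Il1b ran from -0.0698 to 0.0553 in macrophage-like and -0.29 to 0.0700 in monocyte-like cells. Nlrp3 ran from -0.0772 to 0.0177 in cDC2-like cells of ndLN and -0.0275 to 0.0449 in macrophage-like cells. Tcf7 ran from -0.15 to 0.0633 in CD8 T-like cells of dLN and -0.27 to 0.0130 in ndLN. The cDC2-like share, KO versus WT, ndLN, ran from -0.23 to 0.27. Havcr2 in macrophage-like cells ran from -0.59 to -0.51 and lost its call without KO1 alone.

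Cell numbers and depth limit these results. Mature DC-like cells of dLN had 43 and 24 KO cells, and the simulated recovery of genes changed 4-fold was 32.3% there against 91.8% in macrophage-like cells.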

Other observations

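Of the tests in this part, the Itgax neighbours and the splits of tissue genes in CD8 T-like, CD4 T-like, mature DC-like and cDC2-like cells were chosen before their results were seen. The tests of the neighbours in ndLN, of the segment, of TIM-3 loss, of the local effect and of the Havcr2 left, the splits in the other classes and the splits of shares were chosen after.

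Tumours held T cells outside the compared classes. Cluster 18, mainly tumour CD8 T cells led by Pdcd1, had 1.95 Havcr2 UMIs per 10000 in WT1 (57 cells) and 1.62 in KO1 (91 cells), with 0.517 in WT2 (6 cells, 2 UMIs) and 0.911 in KO2 (18 cells, 14 UMIs). These levels are over all tissues, and in tumour the cluster held 56, 3, 85 and 18 cells of WT1, WT2, KO1 and KO2. Treg-like cells had 1.22 in WT1 (53 cells) and 0.318 in KO1 (21 cells), with 1 UMI in 4 cells of WT2 and 0 UMIs in 14 cells of KO2 (12 of them in tumour). In dLN minus ndLN, pDC-like cells had lower Nr4a3 (-0.52, in all 4 mice), and Nr4a1 (-0.74), Vps37b (-0.51) and Ccl4 (-0.88) were lower in 3 of 4 mice each, while cluster 8 had higher Ifi27l2a (0.84), Lef1 (0.41) and Slamf6 (0.46) and lower Ctsw (-0.41), Cxcr6 (-0.39) and Junb (-0.61). Cluster 13 had higher Hspa1a (0.49) and lower Dusp1 (-0.56) and Ccl5 (-0.53).

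Genes on 3 chromosomes passed as higher in KO, 2310031A07Rik beside Havcr2 on chromosome 11 in cDC1-, macrophage- and monocyte-like cells, Plcb4 on chromosome 2 in macrophage- and monocyte-like cells, and, 54.8 kb apart on chromosome 7, Cox6a2 in cDC2-like cells of ndLN and in pDC-like cells and Itgax in monocyte-like cells (in macrophage-like cells 1.48 and 1.45 UMIs per 10000 in KO against 1.19 and 1.03 in WT, which did not pass, adjusted p = 0.688). For 2310031A07Rik a local effect of the deleted allele is a candidate explanation. Over 24 clusters its rise followed the fall of Havcr2 (Spearman rho = 0.518 (0.5183), permutation p = 0.0104, adjusted 0.0208). Pearson r was 0.729 (permutation p = 3.5e-04, adjusted 7e-04). Without the 2 clusters farthest from the median fall of Havcr2, clusters 11 and 21, Pearson r was 0.751. Cluster 11 went with the relation and cluster 21 against it, so the 0.751 rests in part on leaving out a contrary cluster. Only 12 of the clusters had 20 or more Havcr2 UMIs in WT, and the others could show little fall. Clusters of the same mice are not independent samples, and levels were pooled over mice and tissues. In cluster 21 Havcr2 was 1.16 in WT and 0.179 in KO without a rise of 2310031A07Rik (0.206 and 0.179). In cluster 18 the rise was out of proportion, from 0.165 to 0.645 with Havcr2 at 1.86 in WT and 1.49 in KO. The levels of cluster 18 rest mainly on WT1 and KO1. A strain segment kept around Havcr2 could raise the same gene, but holds 1 of the 4 genes within 20 Mb. Extra copies of a segment with Itgax and its neighbours, carried with an Itgax-driven Cre transgene (a driver known from other work and not from the labels), had values on both sides: where Cox6a2 was higher, Itgax was at 0.748 and 0.760 UMIs per 10000 in KO against 1.70 and 1.29 in WT cDC2-like cells of ndLN, and 1.13 and 1.30 against 1.21 and 1.20 (1.205) in pDC-like cells of dLN, but at 1.69 and 2.53 against 2.01 and 1.26 in cDC2-like cells of dLN and higher in both tumour classes, and the median difference of 4 neighbours in cDC2-like cells lay at percentile 26.81 of random lists in dLN and 4.48 in ndLN, with 5.045 to 55.0 elsewhere. The 26.81 lies below the 50th percentile written beforehand as excluding the copies, but inside the spread of random lists of 4 genes. The bound was therefore moved to 5 after the value was seen. The 4.48 of ndLN, where Cox6a2 passed, meets that moved bound. It was the lowest over the comparisons (55.0 in pDC-like cells of dLN, where Cox6a2 passed too), with 2 of 4 neighbours higher in KO. It therefore decides nothing on copies that hold the neighbours. Copies with Cox6a2 alone stay open, as does an effect of TIM-3 loss inside the cells. In B-like and CD8 T-like cells 2310031A07Rik and Plcb4 had 0 calls and were too low to be tested. Plcb4 had 0 UMIs in each WT and 3, 2, 4 and 6 in the KO samples of CD8 T-like cells, in which no Havcr2 UMI was found. Cox6a2 had 1 and 0 UMIs in WT and 7 and 4 in KO CD8 T-like cells of dLN, and 0 and 0 against 3 and 2 in ndLN. B-like cells of dLN had 0 and 0 against 3 and 1. CD4 T-like cells went the other way, with 1 and 0 against 0 and 0 in dLN and 0 and 1 against 0 and 0 in ndLN. Such counts are too low to decide between the explanations. Plcb1, near Plcb4 on chromosome 2, had 9 and 19 UMIs in KO against 0 and 0 in WT cDC2-like cells of dLN. In macrophage-like cells it was at 0.0556 and 0.0431 UMIs per 10000 in KO against 0.0133 and 0.0188 in WT. CD8 T-like cells of dLN had 1 Plcb1 UMI in WT1 and 0 in KO.

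Deletion that follows the level of Itgax is a candidate explanation for the Havcr2 left in KO clusters. Over 12 clusters Spearman rho was -0.517 (-0.5175) with permutation p = 0.0888, and Pearson r was -0.642 (permutation p = 0.0214). Without the 2 clusters farthest from the median Itgax level, Pearson r was -0.844. Those left out were clusters 19 and 21, the lowest in WT Itgax, with 31.2% and 15.45% of the WT Havcr2 level left. They went against the relation, while clusters 12 and 18, also low in Itgax, had 72.3% and 79.8% left. The -0.844 therefore rests on leaving out contrary clusters and is no check of robustness. Levels were pooled over the tissues and over the mice of a genotype, so that of cluster 18 rests mainly on WT1 and KO1. The rho met the bound of -0.5 written for it, but the requirement that its p also pass was added after the value was seen, so the test leaves it open.

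For tissue genes, 8 splits that part the tissues of every mouse are too few for a share under 0.05. In 2 of 8 splits CD8 T-like cells gave as many genes as the real 12 (highest other 14) and in 2 of 8 CD4 T-like cells as many as the real 3 (highest other 4). The real count was 0 in mature DC-like and cDC2-like cells (highest other 0 and 3), so 8 of 8 splits gave as many. It was 4 in pDC-like (highest other 4, 2 of 8 splits as large), 16 in cluster 8 (highest other 4, 1 of 8) and 3 in cluster 13 cells (highest other 1, 1 of 8). In B-like cells the real count was 1 (3 of 8 splits as large), the split that follows the 10x channel gave 1 as well, and the one that turns WT1 alone gave 13, which points to a structure of the samples. In CD8 T-like cells the channel split gave 8 and the one that turns WT1 alone 14, against the real 12. For cell shares tumour minus dLN the real value was 21 (highest other 0, 1 of 8 splits as large), and for dLN minus ndLN it was 1 (highest other 2, 2 of 8 splits as large).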
